A study of Mus musculus with 2 samples.

How the data were processed

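Single-cell RNA sequencing of induced macrophages was analysed from 1 matrix of counts with its gene symbols and barcode names. The labels give 2 samples, a cDNA library and an oligo library, each in a group of its own. Both are described as wild type induced macrophages detached with EDTA and loaded on the DNBelab C4 droplet system, per the labels' protocols. The barcode names carry no sample, so the matrix was treated as 1 sample and no comparison between the 2 libraries was made.

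The deposited values are whole-number counts per gene and barcode, and they are not normalized. They were written by PISA version 0.12, per the file headers, whereas Cell Ranger and the mm10 build are named with no stated role, per the submitters' processing notes. The aligner settings, the gene annotation and the way barcodes were called as cells are not given in the sources used here. That the counts are of unique molecular identifiers is not stated either. If they were of reads, the intervals would be too narrow. The table lists 20034 symbols, each with a count in at least 1 barcode. Of these, 19659 are in GENCODE M21, the annotation of GRCm38 (mm10) from which the coordinates in the text were taken. A symbol without a row was treated as not counted and not as 0. This concerned 76 of the genes in the fixed lists, all of which M21 contains.

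Cells were kept with at least 500 genes and at most 15% mitochondrial counts. These limits were missed by 47 and 50 barcodes, and 86 were left out. Doublets were called with Scrublet (in scanpy 1.11.5, expected share 6%), which marked 0 cells and is taken not to have worked, so doublets were in effect left in. Levels are counts per 1000000 counts (CPM), from counts summed over cells, with exact Poisson intervals. Shares of cells have exact Clopper-Pearson intervals at the 95% level, and the limit for a share of 0 is 3 counts of the total. Intervals of list medians came from 500 Poisson draws. All intervals cover counting error only, and with 1 sample and no replicate no p-value was computed. For shares at equal depth, each cell was thinned to 1900 counts, close below the 10th percentile, which kept 6085 cells.

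For clustering, counts were scaled to 10000 per cell and log-transformed. The 415 list genes with a row were left out, so that none of them shaped the clusters directly. Genes that vary together with them stayed in, so list differences between clusters are not independent of the clustering. The 2000 most variable genes gave 30 principal components. A graph of 15 shared nearest neighbours was parted with the Leiden algorithm (igraph 0.11.9) at resolution 0.5, with clusters numbered by size. A cluster was named for the list with the largest share of detected markers, those with a count in at least 10% of its cells. It stayed unnamed with fewer than 3 detected markers. The same held where another lineage had more of the top 10 genes by fold, or where its median depth was under the sample's divided by 3 with no marker of its own in that top 10. An exploratory clustering was seen before this graph was settled. How to read leading genes that go against a name was settled after the clusters had been seen. So was the choice of the 8 pairs of cluster and list followed through the alternatives. Each cluster was compared with all other cells by the log2 ratio of CPM with a pseudocount of 1 CPM. A list's median was placed among 10000 random lists of the same size drawn from the same 20 bins of mean expression. These were drawn gene by gene and do not keep genes that vary together. Their percentiles are therefore a description and not a test.

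The 21 gene lists and 19 lists of cell type markers were fixed before the data were examined. The rule for named genes was fixed then as well. It names 2 to 6 of the highest members per list over the library, and the 20 highest genes outside ribosomal protein and mitochondrial genes. Between clusters it names the 2 to 4 members with the largest absolute log2 ratio among those at 10 CPM or more, and the 5 leading genes by ratio. Some genes that this rule names are not reported here. Further genes were named after their values had been seen. These are the remaining members of the macrophage and fibroblast lists, Elane and Mpo, Myc in the clusters, the pair of clusters 1 and 8, and all genes of the closing part outside the lists. Only lists that the text discusses for a cluster have members named there. Lists of other nuclear noncoding RNAs, Y-linked genes and endoplasmic reticulum folding factors were added before their values were seen, and a list of transcripts at ribosomal RNA loci after. These extra lists were not left out of the clustering.

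The steps were tested on simulated data made from the totals of the 20034 genes. In pools with 100 genes changed 2-fold and 100 changed 4-fold, median log2 ratios of 0.98 and 1.97 were recovered. This was after the median shift of unchanged genes had been taken off. No such shift was taken off the ratios between clusters reported here. Of 5 lists of genes changed 2-fold, 5 lay at or above percentile 97.5, as against 4 of 100 unchanged lists outside the range of 2.5 to 97.5. In 1000 simulated cells of 2 populations, 97.6% fell in a cluster where their own population was the larger, but 4 clusters were found for the 2 populations. At resolution 0.25 the share was 85.7% and 3 clusters were found. A single simulated population of 1000 cells was parted into 2 clusters, the shallower with a median depth 14.4% of the deeper one's, so clusters can differ by depth alone. Alternatives covered the cell filter, depth, the number of list genes needed, the CPM cutoff, the clustering settings, the pseudocount and the mean of per-cell CPM. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and scikit-learn 1.9.0 were used.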

Results

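Gene expression was measured in single induced macrophages (iMac), mouse cells that the series title describes as made from fibroblasts with the transcription factor c-Myc and no other factor. The labels list a cDNA library and an oligo library from a droplet system (DNBelab C4) and describe the cells of both in the same words, as wild type. The barcode names of the 1 matrix analysed here carry no sample, so it was treated as 1 sample of 1 group. It held 6837 barcodes and 20034 genes with 160606727 counts in all. Counts per barcode ran from 1001 to 192369 with a median of 16743. After 86 barcodes were left out, 6751 cells remained, with a median of 17178 counts and 3160 genes per cell and a median mitochondrial share of 0.568%. There was no replicate and no second group, so no test is possible with 1 sample, and every interval below covers counting error only. Starting fibroblasts, macrophages from animals and other time points were not analysed here.

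The first question the design poses is how far these cells carried macrophage transcripts and how far fibroblast transcripts. All 20 genes of the macrophage list reached 10 CPM (counts per 1000000 counts), and the list median was 247 CPM (95% Poisson interval 245 to 249). Tyrobp, a signalling adaptor of myeloid receptors, stood at 5699.7 CPM (5688 to 5711) with a count in 99.4% of cells. The lysozyme gene Lyz2 was at 3578 CPM, the Fc receptor chain gene Fcer1g at 1502 CPM, Lgmn at 505 CPM and Cd68 at 472 CPM. Csf1r, the receptor for the growth factor CSF1, was at 146 CPM with a count in 72.3% of cells, and Adgre1, which encodes the F4/80 antigen, was at 36.3 CPM and 41.6% of cells. The lowest members were Ms4a7 at 19.9 CPM and Mertk at 11.9 CPM.

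The fibroblast list was almost without counts. Its 11 members with a row had a median of 0.0249 CPM (0.0154 to 0.0499), and none reached 10 CPM. Fstl1 was highest at 1.70 CPM (1.51 to 1.92), followed by Pdgfrb at 0.823 CPM, Loxl1 at 0.455 CPM and Col5a1 at 0.249 CPM, while Pdgfra, Postn and Lox had 1 count each in all kept cells. The other 9 members, Col1a1, Col1a2, Col3a1, Col6a1, Dcn, Lum, Thy1, Fbln2 and Prrx1, had no row in the table of counts, and the median was 0.00624 CPM with these counted as 0. Among 14 fibroblast transcription factors, 7 had a row and none reached 10 CPM, with Tead1 highest at 0.368 CPM. Of 19 extracellular matrix genes, 11 had a row, and the inhibitors of matrix proteases Timp2 (54.4 CPM) and Timp1 (10.4 CPM) were the 2 at 10 CPM or more, and Sparc was at 2.72 CPM.

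**Figure D1:**
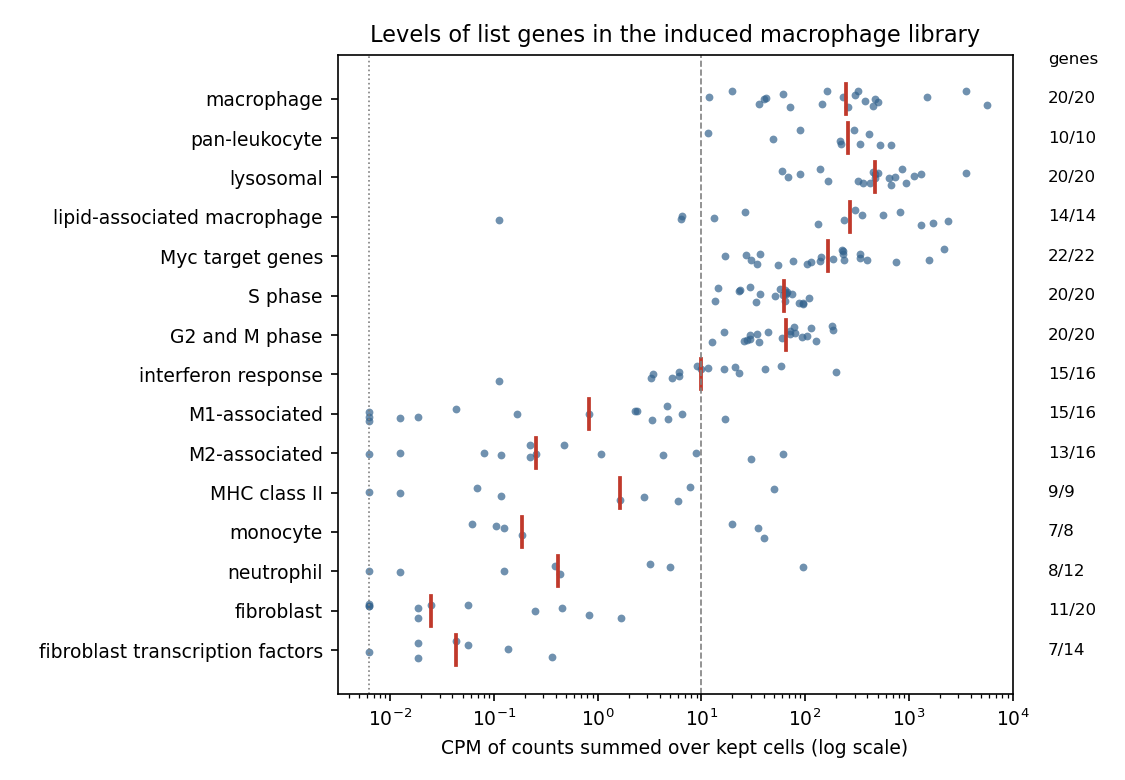
Each point is a gene of the named list at its CPM over all kept cells (log scale), with red bars for list medians, a dashed line at 10 CPM, a dotted line at 1 count, and members with a row over all members at the right. The macrophage list lies above 10 CPM throughout (median 247 CPM) and the fibroblast list below it (median 0.0249 CPM).

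Per cell, 6468 of 6751 cells (95.8%, exact interval 95.3 to 96.3%) had a count for at least 5 macrophage genes. No cell had a count for 5 fibroblast genes, which allows a share of up to 0.0444% of cells with such counts, and no cell met both definitions. This does not limit the share of cells that express fibroblast genes, as 9 members had no row. All 10 pan-leukocyte genes reached 10 CPM, and genes such as Arhgdib (671 CPM) and Coro1a (528 CPM) met the same rule in 84.2% of cells. When each cell was thinned to 1900 counts, which left out 666 shallower cells, the macrophage share was 87.4% and the pan-leukocyte share 27.3%. No cell type known to lack macrophage genes was identified among these cells, so the background share from free RNA was not estimated.

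Other lineages were represented by few transcripts. Of the 17 lists for lineages other than macrophages and leukocytes in general, 16 had a median below 1 CPM, and 5 of their genes reached 10 CPM. These were F13a1 (40.6 CPM), Ly6c2 (35.6 CPM) and Ccr2 (19.99 CPM) of the monocyte list, Prtn3 (96.3 CPM) of the neutrophil list and Nfatc1 (13.2 CPM) of the osteoclast list. The granule protease gene Prtn3 had a count in 44.4% of cells, whereas Elane, another granule protease gene, was at 0.437 CPM and Mpo had no row. Batf3 (7.71 CPM) led the dendritic cell list, Blnk (5.10 CPM) the B cell list, Procr (4.51 CPM) the stem and progenitor list, Eng (3.39 CPM) the endothelial list and Lck (1.34 CPM) the T and NK cell list. Nanog (0.181 CPM) led the pluripotent list, Acta2 (0.493 CPM) the myofibroblast list, and Hdc (0.0561 CPM) the mast cell list. Further leading genes were Klf1 (0.231 CPM, erythroid), Cdh1 (0.181 CPM, epithelial), Itga2b (0.118 CPM, megakaryocyte) and Pax7 (0.0125 CPM, skeletal myoblast). For 1 cell the monocyte list met the rule of 5 genes. That rule says little about the other lists, since 5 of the 17 had fewer than 5 members with a row, such as the mast cell list with 3, and could not meet it, and 5 more had exactly 5.

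Genes with the ribosomal protein symbols Rpl and Rps took 32.3% of counts and mitochondrial genes 0.825%. Among the 20 highest genes outside these groups were Gm42418, Fth1, AY036118, Actb, Fau, Ftl1, Tyrobp, Tmsb4x, Eef1a1, Gm10076, Ppia, Lyz2, Lgals1, Tpt1, Ptma, Cmss1, Gapdh, Rack1 and Lgals3. Gm42418, a noncoding transcript that overlaps a ribosomal RNA locus, took 5.66% of all counts. Fau, which encodes a ribosomal protein under another symbol, was not part of the ribosomal share. The ferritin genes Fth1 and Ftl1 stood at 11564 and 5811 CPM.

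The series names c-Myc as the inducing factor, which makes the level of Myc and of its target genes the next question. Myc (chromosome 15, 61985391 to 61990374, plus strand, GRCm38) was at 40.2 CPM (39.3 to 41.2), with a count in 40.9% of cells. Of the Myc network, 7 of 9 genes with a row reached 10 CPM. The Myc partner Max was at 48.7 CPM, the antagonists Mxd4 and Mnt at 38.3 and 22.0 CPM, and Mycn and Mycl had no row. All 22 Myc target genes reached 10 CPM, with a median of 165 CPM. Ncl and Npm1, which encode nucleolar proteins, were at 2202 and 1563 CPM, and Hspe1 was at 758 CPM. Counts per gene do not separate Myc brought in for the induction from the endogenous gene, and no cells without it were analysed here. The Myc brought in may share or lack the sequence counted, so the level may or may not include it.

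All 20 S phase genes and all 20 G2 and M phase genes reached 10 CPM, with medians of 62.9 and 65.7 CPM. Mcm6, a subunit of the replicative helicase, was at 109 CPM and Pcna, the replication clamp, at 95.3 CPM. Ube2c and Birc5, which act in mitosis, were at 185 and 182 CPM, Top2a at 114 CPM and Mki67 at 105 CPM. At least 5 G2 and M phase genes had a count in 63.3% of cells (62.2 to 64.5%), at least 5 S phase genes in 70.0%, and at least 5 genes of either list in 77.2%. Both rules were met by 56.1% of cells, so they do not part the cells by phase. Once cells were thinned to 1900 counts, the G2 and M phase share was 11.4% (10.6 to 12.2%).

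Of the genes associated with M1 activation, which follows interferon gamma and microbial products, 1 of 15 with a row reached 10 CPM. This was the costimulatory gene Cd86 at 16.9 CPM. Cd38 was at 6.48 CPM and Tnf at 4.83 CPM, and Il6, Nos2 and Il1b had 1 count each in all kept cells. Of the 13 M2-associated genes with a row, 2 reached 10 CPM, the mannose receptor gene Mrc1 at 60.9 CPM and the lectin gene Clec10a at 30.001 CPM. Arg1 was at 0.474 CPM, Cd163 had 2 counts, and Retnla and Chil3 had no row. At 5 CPM the M1 count was 2 and the M2 count 3, and at 50 CPM they were 0 and 1. In MHC class II, Cd74 (50.3 CPM) was the 1 of 9 genes at 10 CPM, with H2-Aa at 0.0686 CPM and Ciita at 1 count. In MHC class I, 9 of 11 genes reached 10 CPM, led by B2m at 677 CPM and H2-D1 at 476 CPM.

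All 20 lysosomal genes reached 10 CPM, with a median of 474 CPM and Ctsz (1327 CPM) and Ctsl (1129 CPM) after Lyz2. Of 18 phagocytic and scavenger receptor genes with a row, 16 did, among them Trem2 (301 CPM), Fcgr3 (234 CPM), Sirpa (194 CPM) and Msr1 (187 CPM), whereas Marco was at 0.0312 CPM. Of 14 genes of lipid-associated macrophages, 11 did, led by Lgals3 (2387 CPM), Apoe (1708 CPM) and Gpnmb (1327 CPM). Among macrophage transcription factors 13 of 16 did, led by Spi1, which encodes PU.1, at 222 CPM, Cebpb at 180 CPM and Irf8 at 114 CPM. Pattern recognition genes gave 10 of 17, led by Pycard (391 CPM) and Cd14 (301 CPM), and interferon response genes 7 of 15, led by Bst2 (199.6 CPM) and Isg15 (59.2 CPM). Chemokines and their receptors gave 9 of 17, with Ccl9 at 423 CPM and Cx3cr1 at 93.9 CPM. Genes that mark macrophages of particular tissues gave 2 of 10, Folr2 (11.8 CPM) and P2ry12 (10.3 CPM), and Vcam1 was listed at 0. All 15 glycolysis genes reached 10 CPM (Gapdh 2780.1 CPM, Ldha 1056 CPM), as did 12 of 15 early response and heat shock genes (Hspa8 1811 CPM, Hsp90aa1 398 CPM) and 9 of 13 p53 response genes (Bax 468 CPM, Cdkn1a 314 CPM). For the 230 list genes at 10 CPM or more, the exact Poisson interval reached at most 4.94% to either side of the value.

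The matrix holds no second group, so the remaining comparison is between clusters of cells within it. Leiden clustering without the list genes gave 9 clusters of 1354, 1154, 918, 888, 763, 618, 527, 504 and 25 cells. Clusters 2, 3, 5, 6, 7 and 8 were macrophage-like by their markers and together held 66.4% of cells (65.3 to 67.5%). Between 13 and 20 of the 20 macrophage genes were detected in each of the 9 clusters, where detected means a count in at least 10% of cells, and no fibroblast gene was detected in any. Cluster 1 stayed unnamed because its leading genes include the monocyte gene Ly6c2 and the neutrophil gene Prtn3. Clusters 4 and 9 stayed unnamed because they were shallow, with medians of 1721 and 4575 counts per cell. Median counts in the other clusters ran from 13291 to 43313, and the values below describe this library only.

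In cluster 2 all 20 macrophage genes were higher than in the other cells, with a median log2 ratio of 0.52 (percentile 100 among 10000 random lists of like expression). Ms4a7 was at 50.4 against 9.41 CPM, Mrc1 at 104 against 46.2 CPM and C1qa, of the complement component C1q, at 476 against 269 CPM. Interferon response genes had a median log2 ratio of 0.94 and all 15 were higher, among them Ifit3 (13.8 against 2.29 CPM), Rsad2 (22.5 against 4.50 CPM) and Isg15 (107 against 42.9 CPM). Chemokine and receptor genes (median 0.70, 16 of 17 higher) included Ccl12 at 12.6 against 3.68 CPM and Ccl4 at 64.9 against 28.5 CPM. Scavenger receptors (median 0.50, 16 of 18 higher) included Fcgr4 at 24.4 against 6.22 CPM and Cd36 at 59.7 against 20.4 CPM. Lipid-associated genes (median 0.52, 13 of 14) and lysosomal genes (median 0.41, all 20) were higher as well. Early response genes were higher too (median 0.43, 13 of 15), with Fos at 60.5 against 30.9 CPM, whereas G2 and M phase genes were lower (median -0.71, 19 of 20), with Kif11 at 10.9 against 31.2 CPM. The leading genes were Ms4a7, Ifit3, Rsad2, Adamts1 and Slfn5. With a pseudocount of 10 CPM in place of 1 CPM, the interferon response median was 0.55.

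In cluster 8, 18 of 20 macrophage genes were higher (median log2 ratio 0.51), with Ms4a7 at 45.4 against 18.5 CPM and C1qb at 564 against 244 CPM. Lipid-associated genes had a median of 0.71 and 13 of 14 were higher, including the lipid droplet gene Plin2 (478 against 224 CPM), Fabp4 (27.4 against 12.5 CPM) and Spp1 (1079 against 540.2 CPM). All 20 lysosomal genes were higher (median 0.42), with the protease genes Ctsd at 1313 against 702 CPM and Ctsb at 1541 against 831 CPM. Interferon response genes (median 0.55, 13 of 15) and chemokine and receptor genes (median 0.55, 12 of 17) were higher in cluster 8 too. The interferon response, chemokine, lipid-associated and lysosomal lists were thus higher in both clusters 2 and 8. All 22 Myc target genes were lower (median -0.66, percentile 0), with Wdr43 at 47.1 against 117 CPM, Nop56 at 81.9 against 194 CPM and Ncl at 999.8 against 2269 CPM. Myc itself was at 19.2 against 41.4 CPM. All 20 S phase genes (median -0.73) and all 20 G2 and M phase genes (median -1.32) were lower, with Hells at 16.6 against 53.045 CPM and Kif20b at 2.49 against 17.3 CPM. The leading genes were Folr2, Ccl6, Rhoc, Ccl7 and Timp2. When all variable genes entered the clustering, the cluster closest to this one shared 0.30 of their joint cells with it (Jaccard index) and its Myc target median was -0.32. The same cluster was also the closest to cluster 2, so cluster 8 had no counterpart of its own there.

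Cluster 1 had lower G2 and M phase genes together with lower macrophage genes. In G2 and M phase 19 of 20 genes were lower (median -1.24, percentile 0), with Kif20b at 3.92 against 18.5 CPM and Top2a at 32.0 against 127 CPM. Of the macrophage genes 17 of 20 were lower (median -0.57), including Ms4a7 (2.49 against 22.7 CPM), Mrc1 (18.3 against 67.9 CPM) and Mertk (5.79 against 12.9 CPM). Interferon response genes had a median of -0.93, with Rsad2 at 2.23 against 10.2 CPM, and scavenger receptors one of -0.63, with Cd36 at 7.92 against 34.1 CPM. Ly6c2 was at 64.0 CPM (60.8 to 67.4) against 30.9 CPM and Prtn3 at 168 CPM against 84.6 CPM. The other leading genes were Ung, Btg2 and 1700034P13Rik.

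Clusters 1 and 8 had nearly the same median depth, 13392 and 13291 counts, and were set against each other after their values had been seen. Ly6c2 was at 64.0 CPM in cluster 1 and 2.61 CPM (1.63 to 3.95) in cluster 8, and Prtn3 at 168 and 20.9 CPM. In the opposite direction, Ms4a7 was at 2.49 and 45.4 CPM, the fatty acid binding protein gene Fabp4 at 2.98 and 27.4 CPM, Spp1 at 188 and 1079 CPM, and Ifit3 at 0.890 and 11.6 CPM. All 20 macrophage genes and all 15 interferon response genes were lower in cluster 1 (medians -0.83 and -1.33), and all 22 Myc target genes were higher in it (median 0.57), with Nolc1 at 186 and 108 CPM. So were 19 of 20 S phase genes and 18 of 20 G2 and M phase genes (medians 0.43 and 0.31), so the higher Myc target genes came together with higher proliferation genes.

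In cluster 3 all 20 S phase genes were higher (median log2 ratio 0.70), with Rrm2, a ribonucleotide reductase subunit, at 116 against 47.7 CPM and Cdc45 at 56.4 against 26.6 CPM. G2 and M phase genes were also higher in 17 of 20 (median 0.52), led by Top2a at 213 against 81.3 CPM, and Myc target genes in 21 of 22 (median 0.25), led by Nop58 at 310.2 against 209 CPM. Its leading genes were the histone genes Hist1h1b, Hist1h2ae, Hist1h2bm, Hist1h1e and Hist1h2an. Cluster 5 was led by Hist1h4h, Hist1h4c, Hist1h4d, Hist1h4a and Hist1h4k, with Hist1h4d at 259 against 44.0 CPM. Its interferon response genes were lower (median -1.08, 14 of 15), with Ifi204 at 8.74 against 24.5 CPM, and all 16 macrophage transcription factors were lower, with Zeb2 at 32.3 against 109 CPM. The median of that list, -0.54, lay at percentile 7.70 of the random lists, which had a median of -0.34 in this cluster.

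Cluster 7 was highest for G2 and M phase genes, all 20 of which were higher (median 1.27, percentile 100). Cenpf was at 113 against 23.2 CPM, Ube2c at 535 against 134 CPM, and Ccnb1, which encodes cyclin B1, at 183 against 55.8 CPM. S phase genes were lower in 18 of 20 (median -0.60), with Ung, a uracil-DNA glycosylase, at 2.20 against 26.7 CPM. Early response genes were lower (median -0.33, 11 of 15), with Fos at 10.4 against 42.5 CPM. Macrophage transcription factors were higher in 15 of 16 (median 0.32, percentile 82.2), among them Zeb2 at 302 against 72.4 CPM and Mitf at 41.7 against 11.3 CPM. The leading genes were Malat1, a noncoding RNA of the nucleus, at 1339.7 CPM (1324 to 1356) against 38.9 CPM, and Gm2245, Kcnq1ot1, Neat1 and Mir99ahg.

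**Figure D2:**
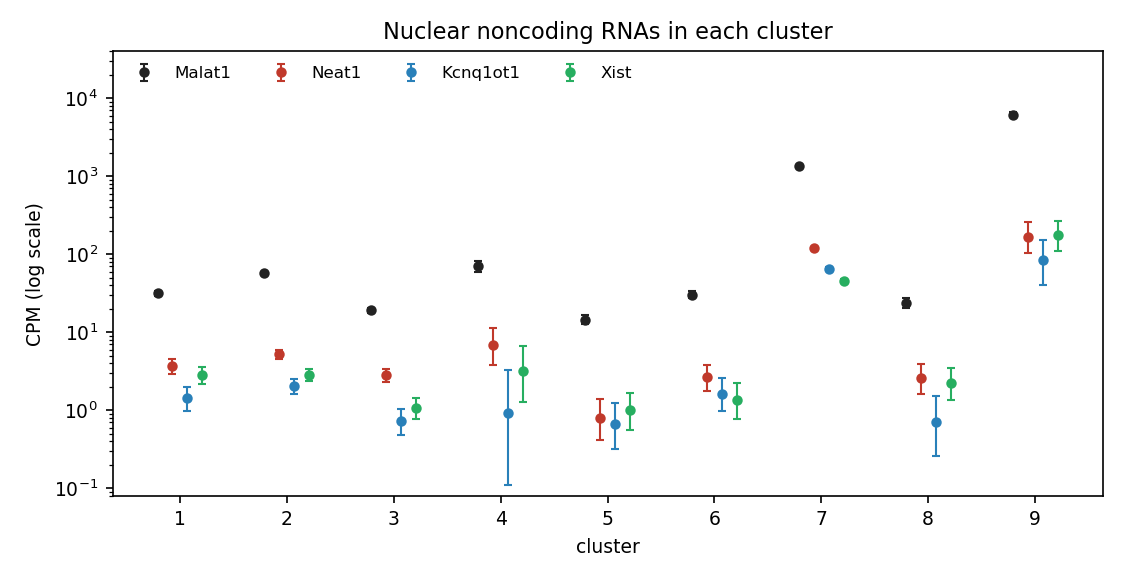
CPM of the noncoding RNAs Malat1, Neat1, Kcnq1ot1 and Xist (vertical axis, log scale) in clusters 1 to 9 (horizontal axis), with exact 95% Poisson intervals that cover counting error only. All 4 stand higher in cluster 7 (Malat1 1339.7 CPM) and in the 25 cells of cluster 9 (Malat1 6140.7 CPM) than in clusters 1 to 6 and 8.

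**Figure D3:**
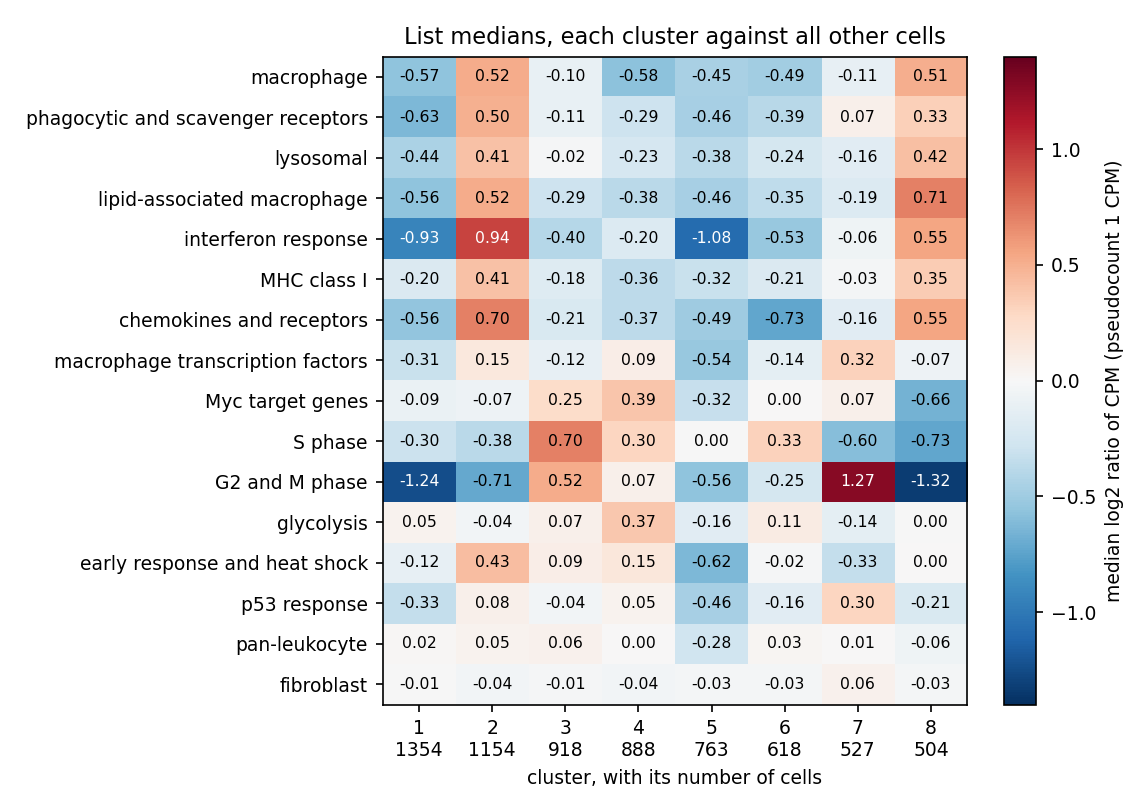
Each square gives the median log2 ratio of CPM over the members of a list (vertical axis), for 1 cluster against all other cells (horizontal axis, with its number of cells), red for higher and blue for lower, with cluster 9 (25 cells) left out. Clusters 2 and 8 are the 2 with the macrophage list above 0 (0.52 and 0.51), and cluster 7 has the highest G2 and M phase median (1.27).

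Cluster 6 was led by Camk1d, Gm48099, D130009I18Rik, Jarid2 and Tmtc2, with Camk1d at 1955 against 399 CPM. It had the lowest median mitochondrial share of the clusters, 0.218%, with Gm42418 at 123029 against 51760 CPM and Lars2 at 1145 against 442 CPM, and the list values that follow stand beside these. Its lipid-associated genes were lower in 13 of 14 (median -0.35), with Spp1 at 128 against 601 CPM, and its macrophage genes in 19 of 20 (median -0.49), with Ms4a7 at 4.64 against 20.99 CPM. S phase genes were higher in 15 of 20 (median 0.33), led by Mcm5 at 122 against 71.9 CPM. Myc was at 69.7 against 38.1 CPM in this cluster, whereas Myc target genes were higher in 12 of 22 (median 0.0047, percentile 96.7). In cluster 4, with a median of 831.5 genes per cell, Myc target genes were higher in 19 of 22 (median 0.39), led by Rcl1 at 44.3 against 26.5 CPM. Macrophage genes were lower in 18 of 20 (median -0.58), with Ms4a7 at 6.85 against 20.1 CPM. Its leading genes were Gm26520, Dguok, Trdmt1, Rpl39l and Atg4a. For list genes at 10 CPM or more, the widest Poisson interval reached 23.5% from the value in cluster 8 and 51.4% in cluster 4.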

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

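The settings without the deepest 5% of cells, with at least 5000 counts, with members without a row counted as 0 and without regard to leading genes were chosen after seeing the data. So were the 8 pairs of cluster and list, though not the settings applied to them. Of 87 values under alternative settings, 43 stayed within the counting interval of the value reported (counts within 1.5 times), 44 moved, and 0 changed sign. Shares, levels and numbers of genes cannot change sign, so the last count bears only on the list ratios between clusters. Some values could not move, such as those with called doublets kept, since 0 were called. The tally is therefore no measure of stability. The share of cells with fibroblast markers and the share with both marker sets were 0 under every setting run. Only the rule of 3 list genes and the setting with no filter on cells could have given another value. The other settings used the same cells, a part of them or of their counts, or a harder rule. No paired analysis was possible because the matrix holds 1 sample.

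With 3 list genes needed per cell, the share with macrophage markers was 99.4% and the share with G2 and M phase genes 77.6%, and with 8 needed they were 86.0% and 46.1%. Cells thinned to equal depth gave 87.4% and 11.4%. These follow from the number of genes or counts required. With no filter on cells the macrophage share was 94.97%, and with at least 1000 genes and at most 10% mitochondrial counts the shares were 99.3% and 71.6%. Cells with at least 5000 counts gave 99.9% and 76.4%, and without the deepest 5% of cells the G2 and M phase share was 61.4%. Depth thus limits both shares.

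With the mean over cells of each cell's CPM, the macrophage median was 251 CPM and Myc 43.97 CPM. In the same setting the macrophage and G2 and M phase lists gave -0.49 and -0.87 in cluster 1, the macrophage list 0.63 in cluster 2, the S phase list 0.62 in cluster 3 and the G2 and M phase list 1.41 in cluster 7. The cause was not tested. With members without a row counted as 0, the fibroblast median was 0.00624 CPM. At 5 CPM 2 M1-associated genes were detected, and at 50 CPM 0 were, with 1 M2-associated gene.

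The share of cells in macrophage-like clusters was 75.3% with no filter, 47.4% with the stricter filter, 63.2% with all variable genes used for clustering, 86.9% at resolution 0.25, 76.2% at resolution 1 and 56.98% with 1000 variable genes and 15 components. It was 86.5% when leading genes were not considered. The cause was not tested, apart from the last, where cluster 1 is named as well.

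A pseudocount of 10 CPM, which shrinks ratios by construction, gave -0.48 and -0.93 for the macrophage and G2 and M phase lists in cluster 1. It gave 0.50 and 0.55 for the macrophage and interferon response lists in cluster 2, 0.62 for the S phase list in cluster 3, 1.05 for the G2 and M phase list in cluster 7 and -0.51 for Myc target genes in cluster 8. Clustering with all variable genes gave, in the cluster closest to each, -0.45 and -1.52 in cluster 1, 0.73 and 1.16 in cluster 2, 0.61 for S phase in cluster 3, and 0.82 for lipid-associated and -0.32 for Myc target genes in cluster 8. Jaccard indices were 0.45, 0.47, 0.76 and 0.30 for these clusters in turn. Clusters 2 and 8 had the same closest cluster, so their values are not separate checks. The cause was not tested. Keeping called doublets moved nothing, since 0 were called.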

Other observations

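The tests of mitochondrial share and of doublets in cluster 7, the latter without shallow clusters added once its first form had been run, the test on fibroblast list members without a row and the overlap of Xist with Y-linked counts were chosen only after the results were seen. In cluster 6, 3 of 4 transcripts tied to ribosomal RNA loci were higher (median log2 ratio 0.85). In the 25 cells of cluster 9, Gm42418 stood at 468947 CPM and Gm26917 at 14502 against 45.6 CPM, with a median mitochondrial share of 7.70%. Genes for folding factors of the endoplasmic reticulum, among them Canx at 214 against 158 CPM, had a median log2 ratio of 0.04 in cluster 7. Barcode names end in a number, and the 3252 barcodes ending in 1 had a median of 8182.5 counts against 24977 for the 1420 ending in 2 and 42210 for the 36 ending in 7, with 30729 for the 16 ending in 8 and 28218 for the 8 ending in 9. What this number stands for is not given in the sources used here, so a technical origin of the depth differences between cells and clusters stays open.

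Malat1 (chromosome 19, 5795690 to 5802672, minus strand, GRCm38) had a count in 29.1% of cells (28.1 to 30.2%), and was higher in cluster 7, the cluster highest for G2 and M phase genes, together with Neat1 (119 against 3.63 CPM) and Kcnq1ot1 (64.8 against 1.36 CPM). Over 14 nuclear noncoding RNAs, the median ratio of cluster 7 to the highest other cluster was 0.750 with the 25 cells of cluster 9 among these. Without the shallow clusters 4 and 9 it was 7.72, and 10 of the 14 stood above the upper limit of every remaining cluster. A mixture would not exceed its source cells, but these values are pooled over each cluster, and single cells can lie above them. Of the 609 cells highest in Malat1, 68.1% were in cluster 7, so others lay elsewhere. These RNAs could also enter the clustering, so cluster 7 may have been gathered by them. Doublets therefore stay open by this test, with cells of the shallow clusters or of the remaining ones. Gm42418, at 468947 CPM in cluster 9, was at 47145 CPM in cluster 7, below every other cluster that was not shallow. Bare nuclei or damaged cells stay open too, with a median mitochondrial share 1.02 times that of the other cells but 0.585 times that of clusters 2 and 3, which are of like depth. A candidate explanation is more nuclear RNA in general: 11 of 11 other nuclear noncoding RNAs were higher (median log2 ratio 1.37), such as Firre (12.6 against 0.801 CPM) and Dleu2 (28.3 against 3.93 CPM), though these genes could enter the clustering. Of the 11, 9 reached 1 CPM in cluster 7 or in the other cells. Peg13 (1.61 CPM) and Gm20544 (0.195 CPM) were below the highest other cluster that was not shallow (1.71 and 0.267 CPM). These RNAs are also of the same class as those to be explained. No biological difference between groups was tested, and whether the pattern belongs to mitosis only cannot be told apart. Of the 609 cells highest in Malat1, 14.8% (12.1 to 17.8%) had fewer than 2 G2 and M phase genes at equal depth. That share lay between the bounds of 10 and 30% set before, and among other cells it was 53.7%. Only the G2 and M phase genes were counted at equal depth. Malat1 was ranked by CPM from all counts of a cell, with 402 CPM the lowest of the 609. Shallow cells with few Malat1 counts could therefore be among them.

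For the 9 fibroblast list members without a row, Col1a1 among them, 2 explanations stay open: that they had no counts, or that these members without a row are missing from the count reference. These cannot be told apart, because all 9 are in the annotation used here and the one used for counting is not given in the sources used here. No biological explanation was tested.

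Xist, the RNA that coats the inactive X chromosome in female cells (chromosome X, 103460366 to 103483254, minus strand, GRCm38), had a count in 5.23% of cells (4.71 to 5.79%). Y-linked genes, such as Eif2s3y (17.2 CPM) and Ddx3y (11.0 CPM), had a count in 35.1% of cells (34.0 to 36.3%), which argues against a culture from females only. That share does not exclude a culture from males only, and here the overlap bears on it: in cluster 7, 27.1% of cells had an Xist count and 54.3% a Y-linked count, but 4.55% (2.94 to 6.70%) had both, against a product of the shares of 14.7%. Over all kept cells the overlap was less far below its product, with 0.933% (0.718 to 1.19%) against 1.84%. Cells pooled from animals of both sexes may account for the low overlap, as a hypothesis found and weighed on the same data. The labels used here give no sex, and no other explanation was tested.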
